A study of Mus musculus with 12 samples.

How the data were processed

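Chromosome conformation capture carbon copy (5C) was measured in mouse cells over the Shh locus. In 5C, crosslinked chromatin is cut and religated, and pairs of oligonucleotides that anneal to ligated fragment ends are joined, amplified and sequenced, so that each read counts a ligation product of 2 named HindIII fragments. The labels give 46c embryonic stem cells (ESC), neural progenitor cells (NPC) made from them in 7 days, and ESC groups named tSBE6-Vp64, tSBE2-Vp64 and tSBE(6+2-Vp64). The t is read here as a TALE, a DNA-binding protein designed for the SBE6 or SBE2 enhancer of Shh, and Vp64 as the transcription activator fused to it. No group transfected with a protein lacking the activator was among those analysed here, and untransfected ESC served as the comparator.

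The deposited matrices hold, per fragment pair, the signal of that pair: the reads of the pair per 1000 reads of the library, as the authors scaled them. This reading was checked on the values, since in each library 100% of the low values (under 20 steps, tolerance 0.05 of a step) were whole multiples of a smallest step. The coordinates are mm9, per the labels and the fragment names. The aligner, the read filters and their versions are not given in the sources used here. The step implies 0.988 to 48.2 M reads (M, mega) per library over the region. Reads of 5C carry no molecular identifiers and are not independent molecules, so depth sets counting error only.

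Fragments absent from any file were left out, which kept 341 fragments on chromosome 5 from 28317087 to 30005000 (median length 2.42 kb). Of 57970 fragment pairs, 28980 were above 0 in at least 1 library. The rest were at 0 in every library and were left out of all means. Whether the assay could measure them was not examined. Each library was scaled to a total of 1000 over these pairs, and technical replicates of a biological replicate were averaged. The NPC library of biological replicate 1, technical replicate 1 and that of biological replicate 2, technical replicate 2 held the same values to within 4.02e-08. The library was therefore counted once, in biological replicate 1. That departs from the design fixed beforehand and was decided after the values were seen; the averages deposited by the authors include it in both replicates. The 12 files thus held 11 distinct libraries, in 8 biological replicates: 2 ESC, 2 NPC, 1 tSBE6-Vp64, 1 tSBE2-Vp64 and 2 tSBE(6+2-Vp64).

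Fragments were assigned by midpoint to 20-kb bins, and the value of a bin pair was its mean over fragment pairs above 0 in any library, with absent pairs at 0. Bin pairs above 0 in at least 2 biological replicates were tested (3439). A second family held 91 pairs among 14 elements, each a window of 20 kb to either side of an approximate mm9 position taken from knowledge of the locus: Insig1, En2, Cnpy1, Rbm33, Shh, the neural enhancers SBE6, SBE4 and SBE2, Rnf32, the limb enhancer ZRS, Lmbr1, Nom1, Mnx1 and Ube3c. An annotation in mm9 coordinates was not used here, so exons and introns are not assigned.

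Values were tested as log2(value + 7.74e-04), the pseudocount being the 5th percentile of bin-pair values above 0, with limma 3.58.1 (lmFit, eBayes with trend, two-sided) in R 4.3.3, all 5 groups in a joint model without covariates. Folds on this scale are shrunk where values approach the pseudocount. Each of 4 groups was compared with ESC at a Benjamini-Hochberg adjusted p of 0.05, over the bin pairs and over the element list alone. The fit left 3 residual degrees of freedom (12.3 in total for bin pairs after moderation), and for element pairs the spread came wholly from the fitted trend. The 2 groups with 1 replicate were assumed to vary like the others. Comparisons of tSBE6-Vp64 with tSBE2-Vp64 and of tSBE(6+2-Vp64) with NPC were added after the data were seen. The domain share and the distance slope were set beforehand to be given as values without a test; an exact two-sided permutation test of 2 against 2 replicates cannot give a p under 0.333.

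The domain share is the percent of signal joining the Shh domain (Shh to the Lmbr1 promoter) with the sequence outside it. The slope is that of log10 mean value on log10 distance from 20 to 1000 kb, in 10 classes per factor of 10. The naming rule took Shh with SBE6, SBE4, SBE2 and ZRS always, any other pair of Shh, SBE6 or SBE2 that passed, and per comparison up to 5 bin pairs each with the largest rise and fall among those passing and moving alike in every replicate, or else the 3 with the smallest p. Groups, tests, elements, naming rule and 25 of 29 alternative settings were chosen before the data were examined. The other 4 settings concern the duplicated library and fragment pairs over 50 kb apart that hold over 0.5% of a library, a limit set after the values were seen. Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 were used for the tables.

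The test was tried on simulated data with log2 changes of known size planted in 50 bin pairs each. At a log2 size of 2, it recovered 1 of 50 for NPC and for tSBE(6+2-Vp64), and 0 of 50 for tSBE6-Vp64 and for tSBE2-Vp64. At a size of 4 it recovered 17, 17, 16 and 11 in that order, and at 6 it recovered 41, 41, 35 and 25. Among element pairs at a size of 2, it recovered 3, 3, 4 and 1 of 5. False calls in these sets numbered 1 to 5 among bin pairs. In 100 sets with no planted change, 14 had at least 1 call. The noise was first drawn from the variances after moderation, which gave more false calls, and was then drawn from the fitted prior; the figures are those of the second form, in which recovery was lower.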

Results

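Contacts across the Shh locus were measured by 5C in mouse ESC, in NPC after 7 days of neural differentiation, and in ESC groups carrying an activator directed at the SBE6 enhancer, the SBE2 enhancer or, by the label, both. Shh encodes a secreted signalling protein that patterns the neural tube and the limb. SBE6, SBE4 and SBE2 are neural enhancers of Shh, and ZRS is its limb enhancer, which lies within Lmbr1. The region covered chromosome 5 from 28317087 to 30005000 (mm9). All values are mean signal per fragment pair, in reads per 1000 reads of the library.

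The libraries differed in depth and in how evenly their reads were spread. Implied depth was 22.0 and 20.7 M reads for the ESC replicates, 43.2, 0.988 and 1.89 M for the 3 distinct NPC libraries, 44.2 M for tSBE6-Vp64 and 48.2 M for tSBE2-Vp64. The 4 tSBE(6+2-Vp64) libraries had 33.2, 38.4, 11.3 and 9.35 M. Fragment pairs above 0 made up 86.7% of the 28980 pairs in ESC replicate 1 and 49.9% in ESC replicate 2, at nearly equal depth. In tSBE(6+2-Vp64) this share ran from 32.9% to 99.7% between libraries. Over fragment pairs, which are not independent replicates, the ESC replicates correlated at 0.577. Technical replicates of tSBE(6+2-Vp64) correlated at 0.544 and 0.506, and libraries of different groups at 0.462 to 0.763.

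A set of 21 long-range fragment pairs took a large part of the reads in some libraries. The pair with the highest signal joined fragment Shh_140 (28763979 to 28767078), beside Shh, with Shh_260 (29166827 to 29168466), between SBE4 and SBE2. It reached 134.7 per 1000 in NPC replicate 1, technical replicate 1. The 21 pairs together held 0.222% and 12.8% of the ESC libraries, 40.5% to 49.7% of the NPC libraries, 3.69% of tSBE6-Vp64, 31.1% of tSBE2-Vp64 and 5.21% to 27.6% of the tSBE(6+2-Vp64) libraries. In the library where it was highest, each exceeded the mean of the pairs within 3 fragments of it by a median of 821-fold (43.4 to 21106). The other pairs of the 21 were left out of that mean. The 21 were picked for a high share of at least 1 library, so high ratios there are no separate evidence.

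**Figure D1:**
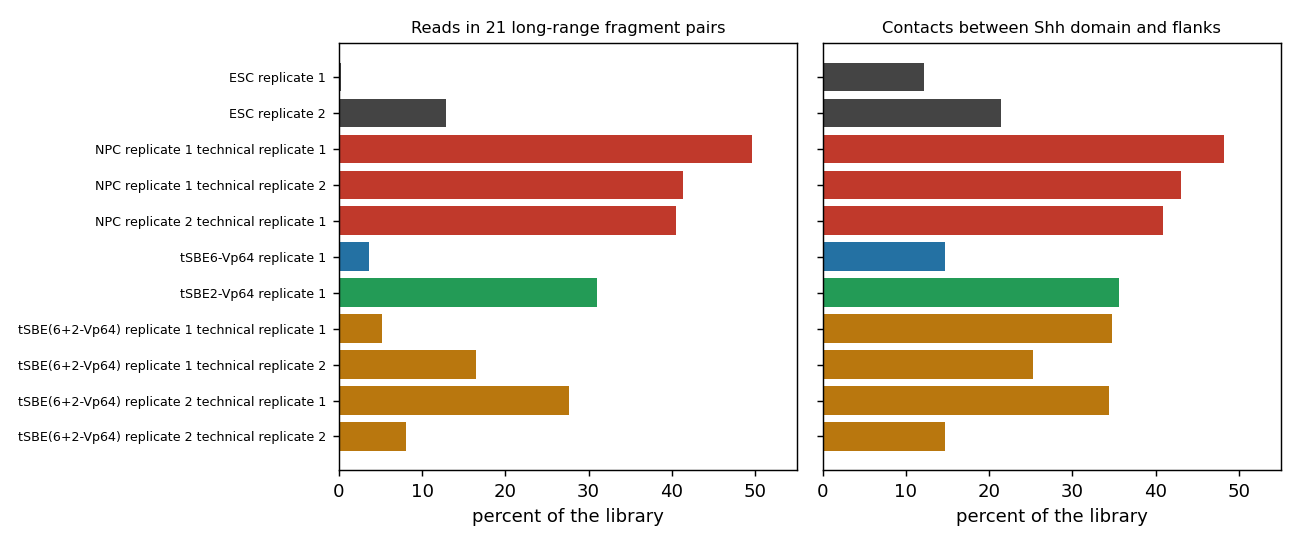
Percent of each of the 11 distinct libraries held by 21 long-range fragment pairs (left) and by contacts joining the Shh domain with its flanks (right), with 1 bar per library, coloured by group. The NPC bars lie between 40.5% and 49.7% on the left and between 40.9% and 48.2% on the right, above both ESC bars in each plot.

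The comparison of NPC with ESC asks how the locus is arranged when ESC take on a neural fate. Contact of Shh with SBE6 was 0.0165 ± 0.0030 (SD, n = 2) in ESC and 0.0179 ± 0.0019 in NPC, a log2 difference of 0.12 (95% interval -1.11 to 1.35). For Shh with SBE4 it went from 0.0191 to 0.0118 (log2 -0.67, SE 0.63) and with SBE2 from 0.0124 to 0.00856 (log2 -0.50, SE 0.65), lower in both NPC replicates than in either ESC replicate. The ZRS contact of Shh was 0.0157 in ESC and 0.0135 in NPC (log2 -0.17, SE 0.63). None of these 4 passed the test, with adjusted p of 0.999 by limma. Relative to the median over all bin pairs (-0.26), SBE6 stood at 0.38, SBE4 at -0.42, SBE2 at -0.25 and ZRS at 0.085. Without the 21 long-range pairs SBE4 was 0.0029, SBE2 0.16 and ZRS 0.50, but the bin-pair median itself moved to 0.34, and relative to it SBE4 was -0.34, SBE2 -0.19 and ZRS 0.16. Relative to the median, SBE6 lay above 0 in 27 of 28 settings, the exception being 40-kb windows (-0.15). SBE4 and SBE2 lay below it in 27 of 28 each, with exceptions at 40-kb windows for SBE4 (3.69) and at 10-kb windows for SBE2 (0.11), and ZRS lay above it in 20 of 28. Of the 91 element pairs, 0 passed by limma, and 4 had an unadjusted p under 0.05, against 4.55 expected by chance.

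Grouped by class, Shh with the 3 neural enhancers had a median log2 difference of -0.50. Shh with the 4 genes on its own side (Insig1, En2, Cnpy1, Rbm33) had -0.76, and Shh with the 3 genes on the far side (Nom1, Mnx1, Ube3c) had -0.34. Of the other 2 genes of the domain, Shh contact differed by 0.058 with Rnf32 and by 1.66 with Lmbr1. The Lmbr1 difference rested on ESC replicate 1 (0.0169), since ESC replicate 2 (0.116) was close to the NPC replicates (0.157 and 0.129), and 1 of the 21 long-range pairs, Shh_154 with Shh_459, lies within it. For SBE6, 10 of its 13 pairs lay above 0 and 3 below, and for SBE2 7 lay above and 6 below. The smallest p belonged to Shh with En2, a homeobox gene of midbrain and hindbrain development, picked out after its values were seen. Its contact was 0.0244 ± 0.0029 in ESC and 0.00477 ± 0.0010 in NPC (log2 -2.19, SE 0.65, adjusted p = 0.0837 by limma), lower in 2 of 2 NPC replicates. It was below 0 in all 27 alternatives (-2.99 to -1.16) and passed in 11 of them. The SBE6 to SBE2 contact, also singled out afterwards, was 0.114 ± 0.123 in ESC and 1.00 ± 0.066 in NPC (log2 3.74, SE 1.28, adjusted p = 0.171 by limma). It was 2.31 without ESC replicate 1, 5.16 without ESC replicate 2 and 1.09 without the 21 long-range pairs, and passed in 5 of 27 alternatives. Of its 70 fragment pairs, Shh_178 with Shh_295 alone had 72.5 per 1000 in NPC replicate 1, technical replicate 1.

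Among the 3439 bin pairs, 4 rose in NPC and 0 fell by limma, with 276 at an unadjusted p under 0.05 (109 higher, 167 lower) against 172 expected by chance. The median log2 difference was -0.26. Bins 28820001 and 29760001, between the sequence just beyond Shh and the Nom1 window, rose from 0.00599 to 0.754 (log2 6.81, SE 0.76, adjusted p = 0.00316 by limma). Bins 29800001 and 30000001, from the Mnx1 window to the end of the region, rose by a log2 of 5.58 (SE 0.74, adjusted p = 0.00625). Bins 28580001 and 29320001 rose by 5.15 (SE 0.64, adjusted p = 0.00480), and bins 29080001 and 29220001, the latter in the SBE2 window, by 4.51 (SE 0.63, adjusted p = 0.00923). Each was higher in 2 of 2 NPC replicates, and 87.2% to 99.8% of each NPC value came from 1 of its 4 to 12 fragment pairs. Without the 21 long-range pairs, the first named bin pair had a log2 of 1.65 and the last 2.71, neither passing, whereas the second had 6.25 and the third 5.82, both passing. The highest fragment pairs of the second and the third are not among the 21, so that setting left them in. Without its own highest fragment pair, the second had a log2 of -1.49 and the third -0.79. Over 25 alternatives the second was at least 4.78 and the third at least 4.33. Leaving out a replicate moved bins 29800001 and 30000001 from 4.78 to 6.40, and bins 29080001 and 29220001 from 3.84 to 5.17. The number of bin pairs passing was not stable: it was 68 without ESC replicate 1, 64 without ESC replicate 2, 13 without NPC replicate 1, 23 without NPC replicate 2 and 0 without either tSBE(6+2-Vp64) replicate. It also came to 0 under 10-kb bins, without the trend in limma, with technical replicates as columns and under both scalings by distance.

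The share of signal joining the Shh domain with its flanks was 16.8% ± 6.49 (SD, n = 2) in ESC and 43.3% ± 3.32 (SD, n = 2) in NPC, with both NPC replicates (45.6% and 40.9%) above both ESC replicates (12.2% and 21.4%). The slope of contact with distance was -0.577 ± 0.138 in ESC and -0.294 ± 0.078 in NPC. With the 21 long-range pairs removed, a setting chosen after the data were seen, the share was 12.3% in ESC and 23.6% in NPC. The slope was then -0.622 in ESC and -0.520 in NPC, and it no longer separated the groups, with -0.571 in NPC replicate 2 and -0.568 in ESC replicate 2. Over pairs more than 50 kb apart, the NPC slope was 0.0327.

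**Figure D2:**
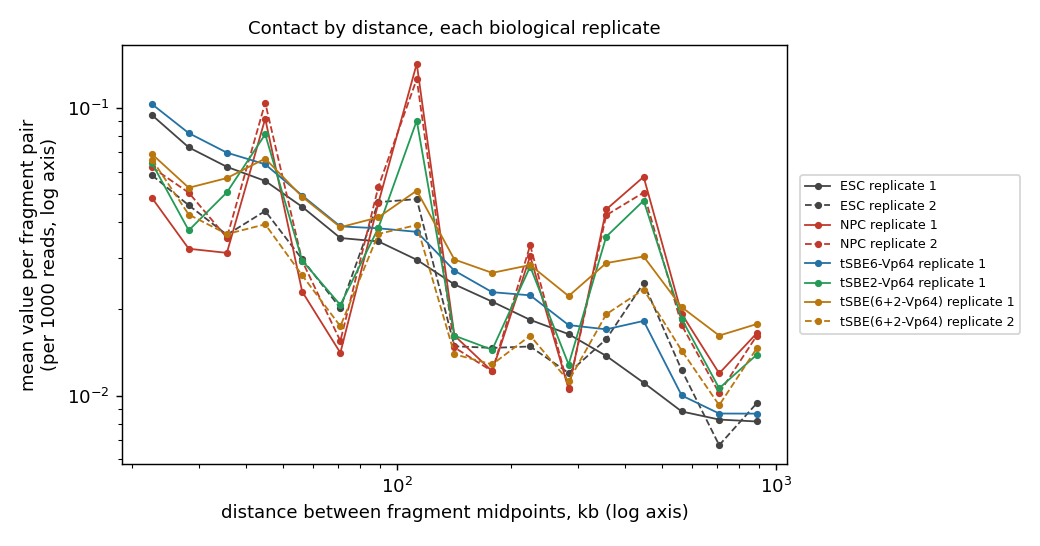
Mean signal per fragment pair (per 1000 reads, log axis) against distance between fragment midpoints (kb, log axis), with 1 line per biological replicate and dashed lines for replicate 2. ESC replicate 1 and tSBE6-Vp64 decline with slopes of -0.675 and -0.657, whereas the NPC lines have peaks at separate distances and slopes of -0.239 and -0.348.

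The comparison of tSBE6-Vp64 with ESC asks how contacts stand when an activator is placed at SBE6. This group had 1 replicate. Contact of Shh with SBE6 was 0.0297 against 0.0165 in ESC (log2 0.83, SE 0.77, adjusted p = 0.972 by limma). With SBE4 the log2 difference was 0.54, with SBE2 0.74 and with ZRS 0.93 (SE 0.77 to 0.80), and in each of the 4 the value lay above both ESC replicates. None passed the test. The median over all bin pairs was itself 0.46, and relative to it the differences were 0.37 for SBE6, 0.07 for SBE4, 0.28 for SBE2 and 0.47 for ZRS. The sign of all 4 was kept under 27 alternatives; relative to the median, SBE4 fell below 0 in 1 of them, at -0.02.

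By class, SBE6 in this group had 12 of 13 pairs above 0, with a median log2 difference of 0.57, and Shh had 9 of 13, with a median of 0.54. Above the bin-pair median of 0.46 lay 8 of 13 and 7 of 13. By limma 0 element pairs passed and 0 had an unadjusted p under 0.05. Among bin pairs 0 passed by limma, and 39 had an unadjusted p under 0.05. The smallest p values, none passing, belonged to 3 bin pairs, each with an adjusted p of 1.00 by limma. Bins 28800001 and 29380001, at the Shh window, had a log2 of -5.89 (SE 1.30) and hold 1 fragment pair. Bins 29380001 and 29820001 had -4.53 and hold 3, and the highest fragment pair of both includes Shh_342. The tSBE6-Vp64 values of these 2 bin pairs, 6.79e-05 and 1.51e-05, lay under the pseudocount (7.74e-04), which bounds the log2 sizes. Bins 28840001 and 29940001, the latter in the Ube3c window, had -3.81. The count was 47 without ESC replicate 1 and 6 without ESC replicate 2. The domain share was 14.7% and the slope -0.657, beside 16.8% and -0.577 in ESC.

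The comparison of tSBE2-Vp64 with ESC asks the same for SBE2, again with 1 replicate. Contact of Shh with SBE2 was 0.0111 against 0.0124 in ESC (log2 -0.13, SE 0.80, 95% interval -1.70 to 1.45). Shh contact differed by 0.02 with SBE6, -0.71 with SBE4 and 0.01 with ZRS on the log2 scale, none passing (adjusted p = 0.999 by limma). By limma 0 of 91 element pairs passed, and 2 had an unadjusted p under 0.05: SBE6 with SBE4 (log2 1.79, SE 0.78) and SBE6 with SBE2 (log2 3.39, SE 1.57). Of the 70 fragment pairs behind SBE6 with SBE2, Shh_178 with Shh_295, 1 of the 21 long-range pairs, alone held 5.12% of the tSBE2-Vp64 library. Of the pairs of SBE2, 6 of 13 lay above 0.

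Among bin pairs 0 passed in tSBE2-Vp64 by limma and 129 had an unadjusted p under 0.05, with a median log2 difference of -0.01. The 3 smallest p values, none passing, came from bin pairs with an adjusted p of 0.108 each by limma. Bins 28580001 and 29320001 had a log2 of 4.78 (SE 0.78) and bins 29800001 and 30000001 of 5.33 (SE 0.90). Bins 28480001 and 29960001, from the En2 window to the edge of the Ube3c window, had 4.72 (SE 0.84). Of these values, 97.5%, 98.5% and 98.3% in that order came from 1 fragment pair. Without it the log2 differences were 0.080, 0.36 and 0.59. For the last bin pair it was Shh_45 with Shh_549, and Shh_549 lies outside the Ube3c window. The count was 40 without ESC replicate 1, 40 without ESC replicate 2, 12 without NPC replicate 1 and 9 without NPC replicate 2. The domain share was 35.6% and the slope -0.351, or 20.7% and -0.532 with the 21 long-range pairs removed.

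The comparison of tSBE(6+2-Vp64) with ESC concerns the label that names both enhancers. Contact of Shh with SBE6 was 0.0208 ± 0.0150 (SD, n = 2) against 0.0165 ± 0.0030 in ESC (log2 0.13, SE 0.63). With SBE4 the log2 difference was -0.02, with SBE2 -0.07 and with ZRS 0.35, none passing by limma. The 2 replicates of this group stood on either side of both ESC replicates for Shh with SBE6, SBE4 and SBE2. For ZRS replicate 1 (0.0266) lay above both and replicate 2 (0.0141) between them. The high values of replicate 1 came from its technical replicate 1, with 0.0453, 0.0384, 0.0287 and 0.0386 for SBE6, SBE4, SBE2 and ZRS. Its technical replicate 2 had 0.0175, 0.0119, 0.0109 and 0.0147 in that order, none above both ESC replicates. Pairs over 50 kb apart held 82.9% of the signal in technical replicate 1, against 48.7% in technical replicate 2. All 13 pairs of SBE6 lay above 0 (median log2 0.34), 7 of them above the bin-pair median of 0.27, and 6 of the 13 pairs of SBE2 lay above 0. The SBE6 values rested on replicate 1: in 9 of these 13 pairs replicate 2 lay below both ESC replicates, and the median over the 91 element pairs was -0.45 without replicate 1 and 0.83 without replicate 2. By limma 0 element pairs passed, and 3 had an unadjusted p under 0.05. The smallest p, picked out afterwards, belonged to En2 with ZRS, 0.00403 in ESC and 0.0183 in tSBE(6+2-Vp64) (log2 2.12, SE 0.69, adjusted p = 0.211 by limma), which passed in 5 of 27 alternatives (0.98 to 2.85).

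Among bin pairs 2 rose and 0 fell in tSBE(6+2-Vp64) by limma, with 108 at an unadjusted p under 0.05. Bins 28820001 and 29760001 rose by a log2 of 5.76 (SE 0.76) and bins 29800001 and 30000001 by 5.25 (SE 0.74), both with an adjusted p of 0.0176 and higher in 2 of 2 replicates. The former was 4.50 without replicate 2 of the group, 6.99 without replicate 1 and 2.17 without the 21 long-range pairs, none passing. The latter was 4.45 without ESC replicate 2, 6.07 without ESC replicate 1 and 5.40, still passing, without the 21 long-range pairs. Its highest fragment pair is not among the 21, and without that fragment pair the log2 was 0.029. Both bin pairs also rose in NPC. In the same order they had 0.0822 and 0.0307 in tSBE6-Vp64 and 0.182 and 0.195 in tSBE2-Vp64, above both ESC replicates but not passing. Higher values than in ESC were thus not particular to NPC and tSBE(6+2-Vp64). The comparisons share the ESC replicates. In 100 simulated sets without change, the mean number of shared calls was 0.02 and the highest 1. That noise was drawn separately for each bin pair and held no single fragment pairs of high signal that recur across libraries. The simulation therefore cannot tell whether such fragment pairs gave the shared calls. The count was 52 without ESC replicate 1, 42 without ESC replicate 2, 5 without NPC replicate 1, 6 without NPC replicate 2 and 0 without either replicate of the group. The domain share was 27.3% ± 3.85 (30.0% and 24.6%) and the slope -0.377 ± 0.014. Within replicate 2, the technical replicates had shares of 34.4% and 14.8%, the latter below ESC replicate 2 (21.4%), and slopes of -0.200 and -0.618. Over pairs more than 50 kb apart, the share of replicate 1 (45.1%) was also below that of ESC replicate 2 (52.0%).

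**Figure D3:**
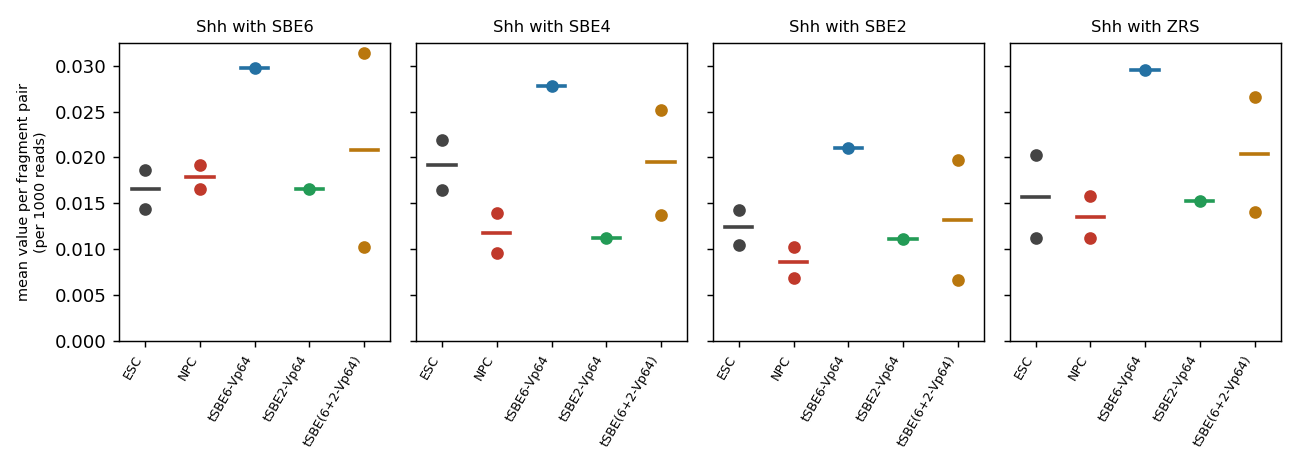
Mean signal per fragment pair (per 1000 reads) between the Shh window and the SBE6, SBE4, SBE2 and ZRS windows, with 1 point per biological replicate and a line at the group mean. The tSBE6-Vp64 point lies above both ESC points in each plot (0.0297 against a mean of 0.0165 for SBE6), and the tSBE(6+2-Vp64) points lie on either side of the ESC points for SBE6, SBE4 and SBE2 but not for ZRS. The higher tSBE(6+2-Vp64) point is a mean of 2 technical replicates, with 0.0453 and 0.0175 for SBE6.

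**Figure D4:**
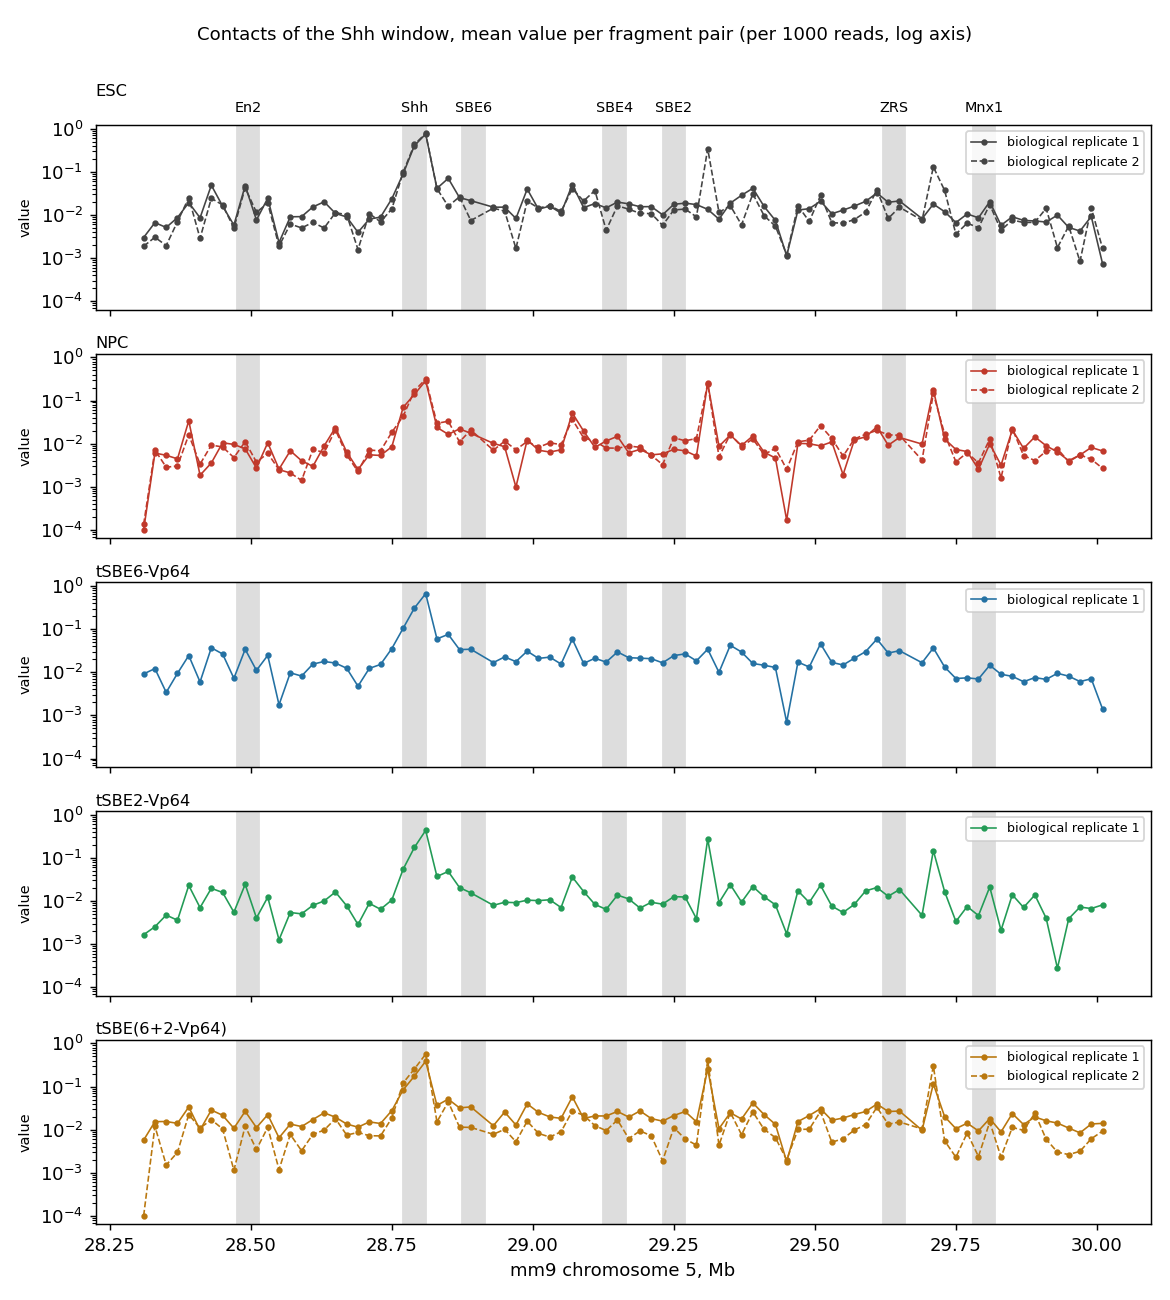
Mean signal per fragment pair (per 1000 reads, log axis, values below the axis floor drawn at it) between the Shh window and each 20-kb bin, against mm9 position on chromosome 5 (Mb), with 1 line per biological replicate, dashed for replicate 2, and element windows shaded. Signal is highest beside Shh, and peaks of 1 bin stand out in NPC, tSBE2-Vp64, tSBE(6+2-Vp64) and ESC replicate 2 but less in ESC replicate 1 and tSBE6-Vp64.

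Comparisons that did not involve ESC, added after the data were seen, gave 0 passing bin pairs and 0 passing element pairs by limma. For tSBE6-Vp64 against tSBE2-Vp64, 101 bin pairs and 0 element pairs had an unadjusted p under 0.05. For tSBE(6+2-Vp64) against NPC these were 180 and 0.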

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

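The tests of the 3 patterns weighed here were chosen after the result was seen, except the test of detected fragment pairs.

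Among the 4 tSBE(6+2-Vp64) libraries, replicate 1, technical replicate 1 stood far above the others in contact of Cnpy1 with Shh (0.0225), Shh with Rnf32 (0.0266) and Shh with ZRS (0.0386). These are 3 of 19 measures tested, and chance gives about 1 in 20 for a single measure. Most of the 19 are contacts of the same Shh window, and this library was highest in all of those but the one with Lmbr1. The measures are therefore not independent, and their count has no fair chance level. Pairs over 50 kb apart held 82.9% of the signal of this library, against 48.7%, 59.8% and 30.2% in the others of the group. Its high signal at long range was thus not particular to these contacts.

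Fragments Shh_68 and Shh_386 lie outside the shared fragments and were listed in 7 of the 12 files, not in the other 5; the duplicated NPC library has 1 file on each side. Their signal per 1000 reads was 9.99 in NPC replicate 1, technical replicate 2, 9.54 in NPC replicate 2, technical replicate 1, and 9.44 in the copy of the duplicated library labelled NPC replicate 2, technical replicate 2. In tSBE(6+2-Vp64) it was 8.57 and 0.0155 in the technical replicates of replicate 1, and 23.9 and 9.71 in those of replicate 2. The ESC files do not list these fragments, so no level in ESC can be set beside them.

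Bin pairs rose in NPC and in tSBE(6+2-Vp64), 6 calls over both comparisons, each with most of its value in 1 fragment pair. Without that fragment pair, 3 of 6 kept a log2 difference above 1 (range -1.49 to 2.13), so the test does not settle the calls as a set. Bins 28820001 and 29760001 fell from 6.81 to 1.19 in NPC and from 5.76 to 2.13 in tSBE(6+2-Vp64). Bins 29080001 and 29220001 fell from 4.51 to 2.02 in NPC. Bins 29800001 and 30000001 fell to -1.49 in NPC and 0.029 in tSBE(6+2-Vp64), and bins 28580001 and 29320001 to -0.79 in NPC. In the bin pairs of the last sentence, the rise lay wholly in 1 fragment pair. Around the highest fragment pair of each call, the median log2 difference was 0.52 (range -2.0 to 1.40), between the bounds set for a contact of the regions and for none. A lone ligation product and a contact between the regions therefore cannot be told apart for the calls as a set, with 6 calls on 4 bin pairs.

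Contacts between the Shh domain and its flanks were higher in NPC than in ESC by 26.5 percentage points. Without the 21 long-range fragment pairs, which held up to 49.7% of a library, the difference was 11.3 points (pooled SD 4.26), which argues against them as the whole cause. The NPC technical replicates of replicate 1, at 43.7-fold different depth, differed by 5.13 points, which argues against depth. By detected fragment pairs alone the difference was 0.712 points, with NPC (44.8% and 42.9%) inside the ESC range (40.0% to 46.3%); this met the outcome written beforehand for uneven amplification, but the test was set aside after its value was seen, since this share was lowest (36.7%) and highest (49.4%) in the libraries with the fewest and most pairs detected. Uneven amplification and a change of the domain with differentiation both stay open, the latter untested.

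Replicates of 1 group differed over fragment pairs, with correlations from 0.409 to 0.964 over 10 pairs of libraries. The libraries with the largest ratio of depths, 43.7-fold, had the highest correlation, 0.964 (next 0.623), which argues against depth. For few ligation products, each read many times, fragment pairs with at least 20 reads in one library and at least 20 expected from it in another of the group were looked up there. In 15 of 20 comparisons 6.70% to 65.7% of them were at 0, where at most 7.76e-07 pairs would be if reads were drawn singly at that level, so a fixed efficiency of each oligonucleotide pair does not account for them. In the other 5 the percent at 0 was 0 to 0.0293. These were between the technical replicates of NPC replicate 1 and towards tSBE(6+2-Vp64) replicate 1, technical replicate 1. The latter library had only 82 of 28980 pairs at 0, so comparisons towards it had little room to meet the bound. The bound set for this explanation was thus not met over the 20 comparisons as a set, and the explanation stays open. A first test, of pairs at 0 against the mean of their distance, was set aside, since a spread of efficiency between pairs would also have met it. A biological difference between replicates was not tested.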

How the results depend on the processing

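The settings on the duplicated library and on the dominant fragment pairs were chosen after the data were seen; the others were planned. Unless a value itself shows otherwise, the cause was not tested.

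The counts of bin pairs passing depended on many settings: over 27 alternatives they ran from 0 to 68 in NPC, 0 to 52 in tSBE(6+2-Vp64), 0 to 47 in tSBE6-Vp64 and 0 to 40 in tSBE2-Vp64. Leaving out each replicate in turn gave those same ranges. The total degrees of freedom of these bin-pair fits ran from 4.97 to 6878, so the counts do not isolate the effect of the replicate left out. For element pairs, leaving out a replicate gave 0 to 3 in NPC, 0 to 4 in tSBE(6+2-Vp64), 0 to 2 in tSBE6-Vp64 and 0 to 3 in tSBE2-Vp64. It also gave ranges for Shh with SBE6 of -0.057 to 0.30 in NPC, -0.66 to 0.89 in tSBE(6+2-Vp64) and -0.16 to 0.20 in tSBE2-Vp64. For Shh with SBE2 these were -0.82 to 0.65 in tSBE(6+2-Vp64) and -0.33 to 0.081 in tSBE2-Vp64. For Shh with ZRS they were -0.57 to 0.24 in NPC, -0.10 to 0.78 in tSBE(6+2-Vp64) and -0.39 to 0.42 in tSBE2-Vp64, and for Shh with SBE4 in tSBE(6+2-Vp64) -0.45 to 0.39. The domain share without a replicate was 12.2% to 21.4% in ESC, 40.9% to 45.6% in NPC and 24.6% to 30.0% in tSBE(6+2-Vp64). Shh with SBE6, SBE4, SBE2 and ZRS in tSBE6-Vp64 kept their sign in all 27 alternatives.

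Bin pairs passing in NPC and in tSBE(6+2-Vp64) numbered 0 and 0 with 10-kb bins, without the trend, with technical replicates as columns, with observed over expected, with totals over pairs more than 50 kb apart, and with dominant pairs removed before observed over expected. With 40-kb bins they were 30 and 17, with 15 in tSBE2-Vp64 and 1 in tSBE6-Vp64. Only pairs above 0 in every replicate gave 30, 12 and 16 in NPC, tSBE(6+2-Vp64) and tSBE2-Vp64. Absent pairs as missing gave 2 and 0 in NPC and tSBE(6+2-Vp64), median-ratio scaling 1 and 0, and a fit of only the groups compared 1 and 17. A pseudocount 5 times higher gave 24 in NPC and 7 in tSBE2-Vp64, and a lower one 0 in tSBE(6+2-Vp64). Removing the dominant pairs gave 15 in NPC, 1 in tSBE(6+2-Vp64) and 2 in tSBE2-Vp64.

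Element pairs passing in NPC numbered 2 with absent pairs as missing, 2 without the trend, 7 with median-ratio scaling (6 higher, 1 lower), 6 with observed over expected (all lower), 18 with totals over pairs more than 50 kb apart (all lower), 4 with 10-kb windows and 7 with 40-kb windows. They numbered 1 with the authors' averages, with only the groups compared, and with either other placing of the duplicated library. In tSBE(6+2-Vp64) they numbered 1, 3, 1, 2, 2 and 4 under absent as missing, median-ratio, observed over expected, totals over 50 kb, 10-kb and 40-kb windows, and 1 with the dominant pairs removed, with or without observed over expected. In tSBE2-Vp64 they numbered 1 without the trend, 3 with median-ratio scaling, 1 with observed over expected, 3 with 40-kb windows and 1 with the dominant pairs removed.

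Scaling moved the median log2 difference of all bin pairs in NPC from -0.26 to 0.34 with median ratios, -0.75 with observed over expected and -1.01 with totals over 50 kb. These shifts are shared by most pairs, so a changed sign under them is not by itself a change of the contact. Values relative to the median, or the median itself, are given beside them. Under the last 2 scalings Shh with SBE6 was -0.22 and -0.72 in NPC (relative to the median 0.53 and 0.29), -0.011 and -0.38 in tSBE(6+2-Vp64) (0.14 and -0.22), and -0.12 and -0.66 in tSBE2-Vp64 (0.36 and -0.027). Shh with ZRS was -0.33 and -0.061 in tSBE(6+2-Vp64) (-0.18 and 0.098) and -0.63 and -0.66 in tSBE2-Vp64 (-0.16 and -0.032). Shh with SBE2 in NPC passed with totals over 50 kb, at -1.32, where the bin-pair median was -1.01. Shh with SBE4 in NPC passed with observed over expected, at -2.11 (median -0.75), and with totals over 50 kb, at -1.51 (median -1.01). The shift shared by most pairs thus makes up much of the differences under totals over 50 kb. Adjusted p over the 27 alternatives ran up to 0.999 for both. With median ratios, Shh with SBE2 was 0.14 in NPC, 0.052 in tSBE(6+2-Vp64) and 0.24 in tSBE2-Vp64, or -0.19, -0.31 and -0.089 relative to the medians (0.34, 0.36 and 0.33), and Shh with ZRS was 0.49 in NPC, or 0.15 relative to it. Over 28 settings, Shh with SBE6 in NPC lay between -0.15 and 1.09 relative to the median, above 0 in 27, and Shh with SBE2 lay below 0 in 27 in NPC, 28 in tSBE(6+2-Vp64) and 26 in tSBE2-Vp64. With values as deposited, Shh with SBE6 and with ZRS in tSBE2-Vp64 were -8.9e-04 and -0.0084.

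With the dominant pairs removed, the bin-pair medians were 0.34 in NPC, 0.37 in tSBE(6+2-Vp64) and 0.37 in tSBE2-Vp64. Shh with SBE2 was 0.16, 0.054 and 0.28 in that order, or -0.19, -0.32 and -0.086 relative to the medians, below them as in the main setting (-0.25, -0.35 and -0.11). Shh with SBE4 was 0.0029 in NPC and 0.052 in tSBE(6+2-Vp64), or -0.34 and -0.32 relative to the medians, and Shh with ZRS was 0.50 in NPC, or 0.16 relative to it. Followed by observed over expected, Shh with ZRS was -0.15 in tSBE(6+2-Vp64) and -0.35 in tSBE2-Vp64, with relative values of -0.15 and -0.30. With absent pairs as missing, Shh with SBE6 was -0.010 in tSBE(6+2-Vp64) and -0.27 in tSBE2-Vp64, and Shh with ZRS -0.37 in tSBE2-Vp64. With only technical replicate 1, Shh with SBE2 was 0.33 in tSBE(6+2-Vp64). With 10-kb windows, Shh with SBE2 was 0.17 and with SBE4 0.53 in tSBE(6+2-Vp64), and with SBE4 0.17 and with SBE6 -0.15 in tSBE2-Vp64. With 40-kb windows, Shh with SBE4 was 3.44 in NPC (adjusted p = 0.0232 by limma), 1.82 in tSBE(6+2-Vp64) and 3.16 in tSBE2-Vp64, where the wider windows take in the pair Shh_140 with Shh_260. Under these windows Shh with SBE6 was -0.41 in NPC, -0.17 in tSBE(6+2-Vp64) and -0.31 in tSBE2-Vp64, Shh with SBE2 1.3e-04 in tSBE(6+2-Vp64) and Shh with ZRS -0.28 in tSBE2-Vp64.

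The domain share with edges 40 kb inwards was 31.4% in NPC and 28.5% in tSBE2-Vp64. With edges outwards it was 31.2% in NPC, 25.7% in tSBE2-Vp64 and 22.8% in tSBE(6+2-Vp64). Over pairs more than 50 kb apart it was 41.9% in ESC, 60.1% in NPC, 33.2% in tSBE6-Vp64, 55.7% in tSBE2-Vp64 and 49.5% in tSBE(6+2-Vp64), and without the dominant pairs 23.6% in NPC, 20.7% in tSBE2-Vp64 and 20.1% in tSBE(6+2-Vp64). The slope over pairs more than 50 kb apart was 0.0327 in NPC, -0.209 in tSBE2-Vp64 and -0.254 in tSBE(6+2-Vp64). Without the dominant pairs it was -0.520, -0.532 and -0.479 in NPC, tSBE2-Vp64 and tSBE(6+2-Vp64). With absent pairs as missing it was -0.431 in ESC, -0.159 in NPC and -0.291 in tSBE(6+2-Vp64).

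The replicate number as a replicate block gave 41 bin pairs in NPC, 14 in tSBE(6+2-Vp64) and 17 in tSBE2-Vp64, with Shh with SBE6 at -0.33 and with ZRS at -0.19 in tSBE2-Vp64. Nothing in the labels says that equal numbers shared a day, and deviations of equal numbers correlated over bin pairs at -0.028 for ESC and NPC, 0.210 for ESC and tSBE(6+2-Vp64) and -0.0051 for NPC and tSBE(6+2-Vp64). The block is therefore given as an alternative; its counts were seen before these correlations.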

Other observations

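Contact of Shh with Lmbr1, whose promoter marks the far edge of the domain, had values of 0.0169 and 0.116 in the ESC replicates, 0.157 and 0.129 in NPC, 0.0334 in tSBE6-Vp64, 0.131 in tSBE2-Vp64, and 0.103 and 0.267 in tSBE(6+2-Vp64). Of the 34 fragment pairs behind these means, Shh_154 with Shh_459 alone held 0.310% of ESC replicate 2, 0.365% to 0.506% of the NPC libraries and 0.378% of tSBE2-Vp64, against 0.0133% of ESC replicate 1 and 0.0554% of tSBE6-Vp64. In the 4 tSBE(6+2-Vp64) libraries it held 0.0134%, 0.594%, 1.26% and 0.200%. None of the differences from ESC passed the test. Contact of SBE4 with Rnf32 was 0.0140 in ESC and 0.0339 in tSBE2-Vp64 (log2 1.24, SE 0.77), also not passing.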
